A study of Homo sapiens with 6 samples.

How the data were processed

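RNA of 6 samples of a human triple-negative breast cancer line was sequenced, 3 of the parental MDA-MB-468 line and 3 of its paclitaxel-exposed derivative. Per the labels' protocols, cells grew in DMEM with 10% serum, and libraries were made from 100 ng of total RNA with a KAPA RNA HyperPrep kit, followed by capture of mRNA with Twist exome probes. The deposited file holds whole-number counts per gene that the authors did not normalise, one column per library, and each column was matched to its sample by the library name in the labels. Trimmomatic 0.38, STAR 2.7.8a and featureCounts of Subread are named, with the genome build GRCh38, per the submitters' processing notes. The strand setting, the treatment of reads with several matches, the annotation release and the featureCounts version are not given in the sources used here. Overlapping, antisense and near-identical genes can therefore exchange reads, and captured fragments without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only.

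The file lists 28395 Entrez gene IDs, of which 9517 had no count in any library. Names and positions came from a RefSeq gene table of GRCh38.p14, which matched 27745 IDs. The 650 unmatched IDs held 0.0327% to 0.0553% of the counts of a library. Pairs of libraries of the same group differed by far more than counting noise (chi-square per degree of freedom 75.5 to 226.9), so each library was counted as a separate sample. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical in part.

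Genes were filtered with filterByExpr by group, which kept 13950, and counts were scaled by TMM. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with the batch year and the group as terms, robust, two-sided, with Benjamini-Hochberg adjustment over all tested genes at 0.05. The design leaves 3 residual degrees of freedom. CPM values are scaled by TMM, standard errors are derived from the F statistic, and a prior count of 2 was used for log2 CPM. Before the data were examined, 50 gene lists were fixed, of which 49 had at least 4 measured members and 1 did not. They were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Counts described as adjusted over the list alone apply the Benjamini-Hochberg method to the members of that list.

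Genes are named by a rule fixed before the data were examined. It takes 11 genes of drug response and immunity whatever their values, the 10 largest rises and 10 largest falls at a mean of at least 5 CPM with one direction in both batches, and in each list up to 2 risen and 2 fallen members at a mean of at least 1 CPM, or its most abundant member where none passed. As the rule allows, members of lists without a call may be left out. LDHB is one of these list members. One gene that the rule takes is not reported here. A ratio is given from summed counts where one group had at most 3 counts in each library, with a 95% Poisson interval, since a fitted fold change then depends on the prior count.

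Replicate numbers in the labels were checked for pairing. Deviations from the group mean of control and resistant libraries with the same number correlated across genes at 0.729, 0.143 and 0.155. As fixed beforehand, the number was also used as a block in place of the batch. The first pair is the 2020 batch. Within 2021 the crossed numbers correlated more, at 0.57 for control 2 with resistant 3 and 0.477 for control 3 with resistant 2. The difference of replicates 2 and 3 in control and resistant cells correlated at -0.361. The values thus gave no ground for pairing by number within 2021, and a block with crossed numbers was added after the data were examined.

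The test was checked on simulated counts for this comparison, with 200 changed genes among 13950 in each of 5 rounds. It recovered 37.2% of genes changed 1.5-fold, 80% at 2-fold, 92.4% at 3-fold and 94.4% at 4-fold, and 10.6% of 850 calls were unchanged genes, above the nominal rate. Both lists moved 1.6-fold were called and 2 of 41 unmoved lists were called as well. Genes were simulated independently of one another, so this rate does not hold for lists whose members are correlated. In the real libraries, the other splits described at the end called 5 to 18 lists. The segment search recovered all 60 genes of a simulated segment. Chromosome segments were runs of windows of 25 neighbouring genes with a median log2 difference of at least 0.4 in size, a search chosen after the data were examined.

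Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, no filter, a minimum mean of 1 CPM, DESeq2 1.42.0, limma voom, no batch term, the replicate block, the 2021 batch alone and leaving out each replicate. GC content and length of transcripts came from GENCODE 29. All columns of the file were used.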

Results

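Gene expression was measured by RNA-seq in MDA-MB-468, an established human triple-negative breast cancer cell line, and in a derivative of it, MDA-MB-468-PR, that had been exposed for 2 months to 3 to 4.5 nM paclitaxel, a drug that stabilises microtubules. There were 3 control libraries of the parental line and 3 libraries of the resistant line, and the labels give all 6 samples as untreated at harvest. All resistant libraries came from this single derivative. An effect of paclitaxel therefore cannot be told apart from other differences that arose while the derivative was made and cultured. The labels place control replicate 1 and resistant replicate 1 in a 2020 batch and the other 4 libraries in a 2021 batch. Libraries were enriched by capture with exome probes, so transcripts outside the probe set are counted less completely than protein-coding ones. The total count was 41343499, 59171296 and 66475627 in control replicates 1 to 3 and 37889818, 63073979 and 93680129 in resistant replicates 1 to 3. At these depths 3 counts, the limit that a count of 0 allows, corresponded to 0.0311 to 0.0808 CPM. The title of the series asks about factors secreted by resistant cells and their effect on immune cells, so secreted factors are reported beside drug handling, matrix and growth genes.

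The resistant line differed from the control line in 1633 of 13950 tested genes (11.7%), of which 869 were higher and 764 lower (edgeR quasi-likelihood test with the batch as a term, Benjamini-Hochberg adjusted p under 0.05). A change of at least 2-fold was found in 560 of them, 427 higher and 133 lower. Of the 1633 genes, 1340 separated the 3 resistant from the 3 control libraries without overlap. Over all tested genes 20.9% were so separated, against 10% by chance. The batches themselves differed in 3196 genes, and without the batch term 362 genes passed the threshold. Leaving out resistant replicate 3 gave 617 genes, resistant replicate 2 gave 851, resistant replicate 1 gave 1001 and control replicate 1 gave 1064. The count at 2-fold fell to 333 without resistant replicate 3.

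Among genes at a mean of at least 5 CPM, the largest fitted rise was in KLHL29, a kelch-family gene, from 1.59 ± 0.619 to 17.6 ± 10.3 CPM (SD, n = 3 per group), a fitted 10.3-fold difference (log2 fold change 3.37 ± 0.22 SE, adjusted p = 0.000654). COL12A1, which encodes a collagen, rose 7.51-fold to 215 ± 61.5 CPM, and FBN1, which encodes the microfibril protein fibrillin-1, rose 5.17-fold to 21.4 ± 5.04 CPM. KIF1A, a kinesin motor, rose 7-fold. ADAMTS1, a secreted metalloprotease, rose 6.99-fold, and GJB2, a gap junction protein, rose 6.43-fold. The calcium-binding proteins CALB2 and VSNL1 rose 5.76-fold and 5.63-fold. The transcription factor MEF2C rose 5.61-fold and the guanine deaminase GDA rose 5.1-fold. For these 10 genes the adjusted p lay between 0.000654 and 0.0263. With the replicate number as a block the adjusted p was 0.057 for COL12A1 and 0.0911 for ADAMTS1. Without control replicate 1 or resistant replicate 1 the calls of COL12A1 and GDA ended, with adjusted p up to 0.104 and 0.0993. ADAMTS1 lost its call without any control replicate or resistant replicate 1 (up to 0.197), and KIF1A and GJB2 without control replicate 3 (adjusted p = 0.0736 and 0.0528).

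Among genes at a mean of at least 5 CPM, the largest fitted fall was in GSTP1, which encodes a glutathione transferase that conjugates electrophilic compounds (Entrez gene 2950, chromosome 11, 67583812 to 67586653, GRCh38). It had 418, 1342 and 425 counts in the control libraries and 0, 1 and 1 in the resistant libraries. The control to resistant ratio was 1330, with a 95% counting interval of 369 to 11000 (adjusted p = 0.00326). Without resistant replicate 1 the adjusted p was 0.0531. HSD17B2, an enzyme that oxidises oestradiol, fell 6.71-fold from 33.3 ± 7.17 to 4.99 ± 1.01 CPM (adjusted p = 0.000672). STS, the steroid sulfatase, which lies in the chromosome X segment described below, fell 3.15-fold from 69.3 ± 6.6 to 22.1 ± 1.85 CPM (adjusted p = 0.000654). KRT14, a basal keratin, fell 4.26-fold (adjusted p = 0.000894), and CLCA2, SLC6A14 and ADAMTS4 fell 2.96-fold, 2.91-fold and 3.12-fold. The pseudogene CYP4Z2P fell 4.46-fold and OBP2B 5.03-fold, and both, like KRT14, have close relatives with which reads may be shared. The non-coding LINC03040, in the chromosome 6 segment described below, fell 3.19-fold, with an adjusted p of 0.0692 under the replicate block. LINC03040 lost its call without control replicate 1 or 3 or resistant replicate 1 (adjusted p up to 0.122), and OBP2B without control replicate 1 or any resistant replicate (up to 0.117).

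**Figure D1:**
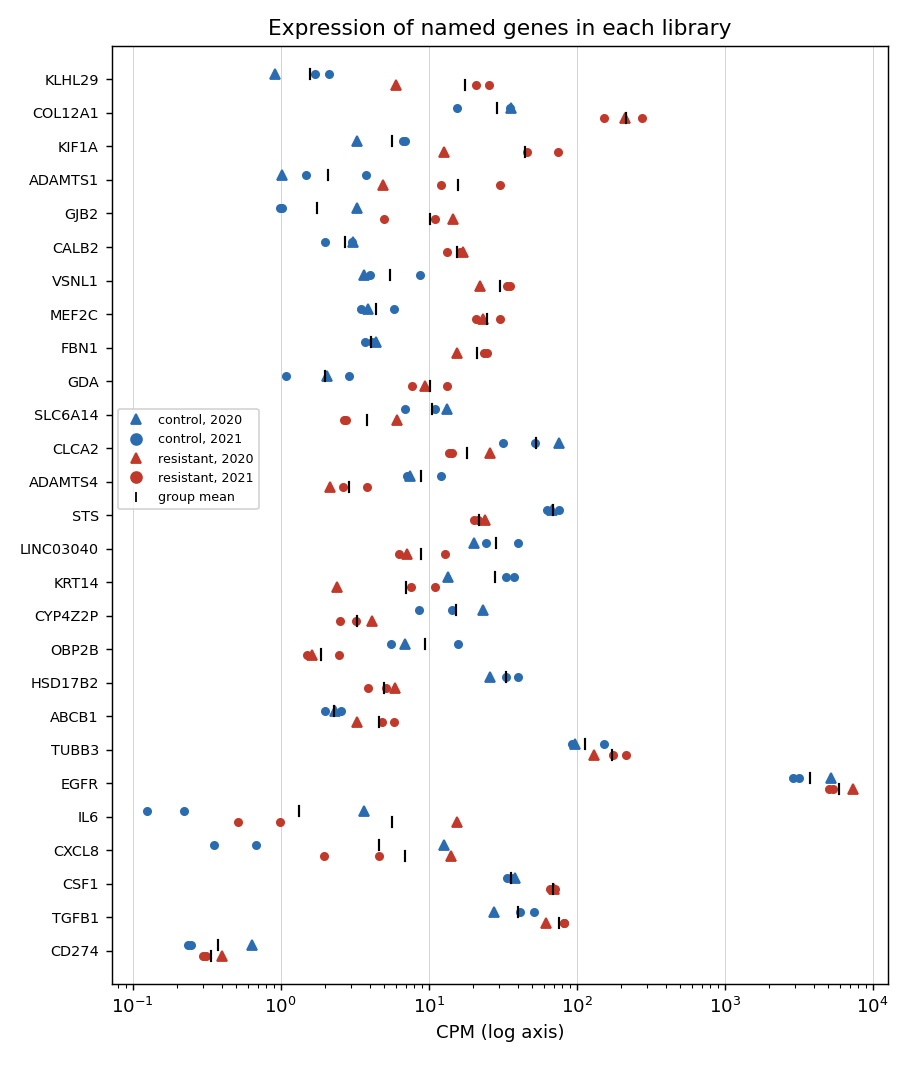
CPM of each library (horizontal log axis) for the 10 genes with the largest rise, 9 of the 10 with the largest fall, each at a mean of at least 5 CPM, and the reported genes named beforehand, with 2020 libraries as triangles, 2021 libraries as circles, control blue, resistant red, and the mean of 3 as a black bar. GSTP1, at 0 to 0.015 CPM in the resistant libraries, is not drawn; in KLHL29 each resistant library lies above each control library, while IL6 and CXCL8 are higher in both 2020 libraries than in the 2021 libraries of the same line.

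Of 49 gene lists fixed in advance with at least 4 measured members, 22 were called by the camera set test at an inter-gene correlation preset to 0.01, 15 higher and 7 lower in the resistant line. None was called when the correlation was estimated from these libraries, where 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.52. That test rests on the 3 residual degrees of freedom and has little power here, so it does not show that no list changed. Cholesterol synthesis, with 0 of 24 members above 0, also had 0.52 in it. In the simulation, where genes were independent, it called both moved lists. The 27 lists not called had adjusted p of 0.056 to 0.86. The self-contained test fry, which asks whether a list moved on balance in one direction, called 5, each also called by camera: cholesterol synthesis lower, and interleukins and haematopoietic cytokines, type I interferon response, YAP and TEAD targets, and Notch and Wnt targets higher.

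**Figure D2:**
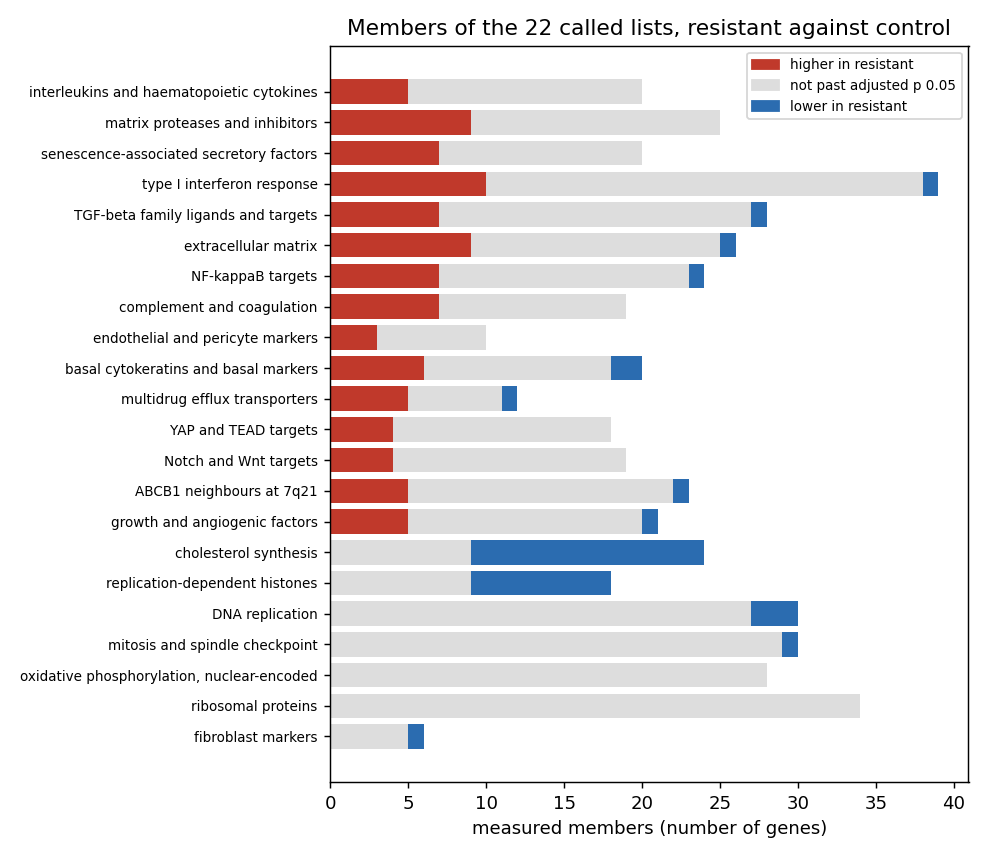
Number of measured members (horizontal axis, genes) of each called list that were higher in the resistant line (red), lower (blue) or not past an adjusted p of 0.05 (grey). Cholesterol synthesis holds 15 lower members of 24, and no member of the oxidative phosphorylation or ribosomal protein list passed.

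Genes that handle drugs changed in both directions. Among 12 measured multidrug efflux transporters 5 rose and 1 fell (6 and 1 adjusted over the list alone), and the list was called higher (adjusted p = 0.018; adjusted p = 0.53 with an estimated correlation). ABCC4, an exporter of organic anions, rose 2.13-fold from 24.5 ± 4.7 to 52.1 ± 4.76 CPM (log2 fold change 1.09 ± 0.15 SE, adjusted p = 0.00302). ABCB1, which encodes the P-glycoprotein pump that exports paclitaxel, rose 1.99-fold from 2.3 ± 0.293 to 4.64 ± 1.31 CPM (0.99 ± 0.23 SE, adjusted p = 0.0251). Its log2 difference was 0.47 in 2020 and 1.22 in 2021. The call of ABCB1 ended without control replicate 2, resistant replicate 2 or resistant replicate 3, with adjusted p up to 0.14. ABCC10, another exporter, fell 1.66-fold and lies in the chromosome 6 segment. Of 23 measured genes of ABCB1 and its neighbours on chromosome 7, 5 rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.025, and adjusted p = 0.55 with an estimated correlation). The kinase gene CDK14 rose 3.53-fold and CYP51A1, which also belongs to cholesterol synthesis, fell 1.39-fold. CDK14 lost its call without resistant replicate 3 (adjusted p = 0.0506), and CYP51A1 without control replicate 1 or any resistant replicate (up to 0.0998). That neighbour list lost its call without control replicate 2 or resistant replicate 3 (adjusted p up to 0.179) and without the batch term (0.0628).

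Tubulins and proteins that bind microtubules changed gene by gene. TUBB3, the beta-III tubulin, was at 115 ± 33.5 CPM in control and 175 ± 43 CPM in resistant libraries, a difference that did not pass (log2 fold change 0.59 ± 0.19 SE, adjusted p = 0.084). It passed without control replicate 2 (adjusted p = 0.0486) and with DESeq2 (0.0193). Among 14 measured tubulins 1 rose and 1 fell (3 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.55). TUBA1A rose 1.53-fold, a call that ended without control replicate 1 or 2 or resistant replicate 1 or 2 (adjusted p up to 0.142). TUBB2A, which has a near-identical neighbour and lies in the chromosome 6 segment, fell 1.57-fold, with an adjusted p of 0.054 under the replicate block. It lost its call without each replicate except control replicate 3 (adjusted p up to 0.155). Of 25 microtubule-associated genes 2 rose and 1 fell (2 and 2 adjusted over the list alone), and this list was not called either (adjusted p = 0.83). MAP1B, a microtubule-stabilising protein, rose 3.2-fold to 63.3 ± 17.4 CPM (adjusted p = 0.00247), and HDAC6, a tubulin deacetylase in the chromosome X segment, fell 2.11-fold (adjusted p = 0.00126). EGFR, the epidermal growth factor receptor (chromosome 7, 55019017 to 55211628, GRCh38), rose 1.61-fold from 3770 ± 1260 to 5960 ± 1230 CPM (log2 fold change 0.69 ± 0.15 SE, adjusted p = 0.0199). Its difference was 0.5 in 2020 and 0.79 in 2021, and the call ended without control replicate 1 or any resistant replicate (adjusted p up to 0.0853).

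Among secreted immune factors, several cytokine genes were higher in the resistant line. Of 20 measured interleukins and haematopoietic cytokines 5 rose and none fell (8 and 0 adjusted over the list alone; list adjusted p = 2.9e-05, and adjusted p = 0.52 with an estimated correlation). CSF1, the macrophage colony-stimulating factor, rose 1.93-fold from 36 ± 2.05 to 69.5 ± 3.24 CPM (log2 fold change 0.95 ± 0.09 SE, adjusted p = 0.00119). IL15, which sustains T and NK cells, rose 2.46-fold to 3.41 ± 0.987 CPM (adjusted p = 0.00667). IL6, an inflammatory cytokine, rose 4.21-fold (adjusted p = 0.00443), by 2.07 on the log2 scale in 2020 and 1.91 in 2021. IL6 depended strongly on the batch, with 3.65 CPM in control and 15.5 CPM in resistant cells in 2020 against 0.13 to 0.99 CPM over the 4 libraries of 2021. CXCL8, the neutrophil chemokine interleukin-8, showed a log2 difference of 0.14 in 2020 and 2.54 in 2021 and did not pass (adjusted p = 0.209). Without the control or the resistant library of 2020 it passed (adjusted p = 0.0339 and 0.0329). CCL2 and CSF2 were too low to test. CCL2 had 1, 0 and 4 counts in control replicates 1 to 3 and 5, 48 and 8 in resistant replicates 1 to 3. CSF2 had 0 to 3 counts per library. Of 11 measured chemokines 1 rose and 3 fell (1 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.86). CXCL1, a neutrophil attractant, rose 5.33-fold to 2.8 ± 0.965 CPM, with an adjusted p of 0.0517 under the replicate block. Its log2 difference was 0.83 in 2020 and 3.1 in 2021. CCL22, which attracts regulatory T cells, fell 2.25-fold. CXCL1 lost its call without control replicate 2 or 3 or resistant replicate 3 (adjusted p up to 0.149), and CCL22 without resistant replicate 2 or 3 (up to 0.0997).

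The TGF-beta list had 7 members higher and 1 lower of 28 (9 and 2 adjusted over the list alone; list adjusted p = 0.003, and adjusted p = 0.55 with an estimated correlation). TGFB1 rose 1.92-fold from 40.1 ± 11.9 to 75.7 ± 11.9 CPM (log2 fold change 0.94 ± 0.12 SE, adjusted p = 0.00248), whereas TGFB3 fell 2.56-fold. INHBA, the activin A subunit, rose 2.58-fold to 4.1 ± 2.19 CPM. INHBA lost its call without control replicate 2, resistant replicate 2 or resistant replicate 3 (adjusted p up to 0.134), TGFB3 without resistant replicate 3 (0.0912) and the list without control replicate 3 (0.0561). Of 20 senescence-associated secretory factors 7 rose (8 up and 1 down adjusted over the list alone; list adjusted p = 0.00073, and adjusted p = 0.53 with an estimated correlation), led by CXCL1 and IL6. Its median log2 difference was 0.136 in 2020 and 1.003 in 2021, and that of the NF-kappaB targets 0.096 and 0.604. Of 24 NF-kappaB targets 7 rose and 1 fell (8 and 1 adjusted over the list alone; list adjusted p = 0.0092, and adjusted p = 0.55 with an estimated correlation), and that list's call ended without resistant replicate 2 (0.0609). NFKBIE, an inhibitor of NF-kappaB in the chromosome 6 segment, was the member that fell, by 1.57-fold. Its call ended without each replicate except control replicate 3 (adjusted p up to 0.147).

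Some interferon response and complement genes rose. Of 39 type I interferon response genes 10 rose and 1 fell (12 and 2 adjusted over the list alone; list adjusted p = 0.0028, and adjusted p = 0.52 with an estimated correlation). IFI44 rose 3.5-fold to 7.35 ± 3.7 CPM (adjusted p = 0.00522) and XAF1 rose 2.77-fold to 4.06 ± 2.07 CPM, while OAS1, a sensor of double-stranded RNA, fell 1.51-fold. XAF1 lost its call without resistant replicate 3 (adjusted p = 0.0526). OAS1 had an adjusted p of 0.0517 under the replicate block and lost its call without control replicate 2 or any resistant replicate (up to 0.179). Of 19 complement and coagulation genes 7 rose (10 up and 3 down adjusted over the list alone; list adjusted p = 0.01, and adjusted p = 0.52 with an estimated correlation). TFPI2, a serine protease inhibitor, rose 3.9-fold to 18.7 ± 3.54 CPM (adjusted p = 0.0014), and CFI, which encodes complement factor I, rose 3.71-fold to 18 ± 11.7 CPM. The call of CFI ended without control replicate 1 or resistant replicate 1 (adjusted p up to 0.109). Of 16 MHC class I presentation genes 1 rose and 1 fell (1 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.64). CD274, which encodes PD-L1, was at 0.377 ± 0.233 and 0.34 ± 0.0558 CPM, with a log2 difference of -0.64 in 2020 and 0.31 in 2021, and did not pass (adjusted p = 0.999). Among 22 ligands of T-cell and NK-cell receptors 3 rose and 1 fell (4 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.084). It was called higher without control replicate 1 or resistant replicate 1 (adjusted p = 0.0289 and 0.0296). The death receptor FAS rose 3.8-fold to 12.5 ± 9.04 CPM (adjusted p = 0.000654), and NT5E, the CD73 enzyme that makes adenosine, rose 2.22-fold from 94.6 ± 21.4 to 208 ± 15.6 CPM (adjusted p = 0.00223).

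Some genes of the extracellular matrix and of its proteases rose in the resistant line. Of 25 matrix proteases and inhibitors 9 rose and none fell (13 and 0 adjusted over the list alone; list adjusted p = 0.00021, and adjusted p = 0.52 with an estimated correlation). Besides ADAMTS1, the kallikrein KLK7 rose 1.99-fold, a call that ended without control replicate 1 or any resistant replicate (adjusted p up to 0.0831). ADAMTS4, of the same family as ADAMTS1 but outside the fixed list, fell 3.12-fold (adjusted p = 0.00408). Of 26 extracellular matrix genes 9 rose and 1 fell (11 and 2 adjusted over the list alone; list adjusted p = 0.0052, and adjusted p = 0.53 with an estimated correlation). Besides COL12A1, COL4A2, which encodes a basement membrane collagen, rose 4.41-fold from 38.9 ± 9.49 to 179 ± 66.2 CPM (log2 fold change 2.14 ± 0.16 SE, adjusted p = 0.000654). Growth and angiogenic factors had 5 members higher and 1 lower of 21 (5 and 2 adjusted over the list alone; list adjusted p = 0.04, and adjusted p = 0.53 with an estimated correlation). IGFBP5, a binding protein of insulin-like growth factors, rose 2.6-fold to 115 ± 40.8 CPM (adjusted p = 0.0085). The call of IGFBP5 ended without control replicate 1 or resistant replicate 1 (adjusted p up to 0.052), and that of the list without either of these or control replicate 2 (up to 0.0592). That list was also not called under upper quartile scaling (0.06), with no filter (0.0598), without the batch term (0.0944) or in 2021 alone (0.0636). Of 18 mesenchymal genes 3 rose and 1 fell (5 and 2 adjusted over the list alone), and of 30 epithelial genes 1 fell (0 adjusted over the list alone). Neither list was called (adjusted p = 0.12 for both), but the mesenchymal list was called higher without resistant replicate 3 (0.0318).

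Markers of breast lineages changed one by one. Of 20 basal cytokeratins and basal markers 6 rose and 2 fell (9 and 2 adjusted over the list alone; list adjusted p = 0.018, and adjusted p = 0.53 with an estimated correlation). TP63, the basal transcription factor p63, rose 3.87-fold from 5.25 ± 0.495 to 20.8 ± 7.88 CPM (adjusted p = 0.00667), and the laminin gene LAMB3 rose 2.1-fold. KRT14 and the small heat shock protein CRYAB, by 1.79-fold, fell. TP63 lost its call without control replicate 2 or 3 (adjusted p up to 0.0716), LAMB3 without resistant replicate 3 (0.0526), and the list without control replicate 1 or 3 or resistant replicate 1 (up to 0.0697). The basal list was also not called in 2021 alone (0.0586) or with no filter (0.0555), where its mean log2 fold change relative to all genes turned from 0.24 to -0.06. Of 16 luminal markers 1 rose and 2 fell (1 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.12), but it was called lower without resistant replicate 1 (0.0337) and with no filter (0.0393). SPDEF, a luminal transcription factor in the chromosome 6 segment, fell 2.62-fold from 140 ± 41.2 to 52.5 ± 4.08 CPM (adjusted p = 0.00203). YAP and TEAD targets had 4 of 18 members higher (4 up and 1 down adjusted over the list alone; list adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation), NT5E among them. Of 19 Notch and Wnt targets 4 rose (4 adjusted over the list alone; list adjusted p = 0.023, and adjusted p = 0.52 with an estimated correlation). The Notch ligands JAG2 and JAG1 rose 2.79-fold and 1.52-fold (adjusted p = 0.000654 and 0.0103). JAG1 lost its call without resistant replicate 3 (0.0565), the Notch and Wnt list without control replicate 3 (0.0701), and the YAP list without control replicate 1 or 3 or resistant replicate 1 (up to 0.0658). The Notch and Wnt list was also not called at a mean of at least 1 CPM (0.1145), with no filter (0.05003) or without the batch term (0.0503), and the YAP list in 2021 alone (0.0539).

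Markers of cells that a culture of this line should not hold moved in both directions. Endothelial and pericyte markers had 3 of 10 members higher (4 adjusted over the list alone; list adjusted p = 0.012, and adjusted p = 0.52 with an estimated correlation). MCAM, an adhesion molecule also made by tumour cells, rose 2.54-fold to 17.4 ± 6.93 CPM (adjusted p = 0.00148). ESAM rose 1.9-fold to 4.93 ± 1.38 CPM, with an adjusted p of 0.0502 under the replicate block. Of 6 fibroblast markers 1 fell (3 adjusted over the list alone; list adjusted p = 0.046, and adjusted p = 0.53 with an estimated correlation). Of 5 leukocyte markers none passed, also adjusted over the list alone (list adjusted p = 0.57), and 1 of 18 erythroid and hepatic markers was measured. Transcripts that follow dissociation or RNA quality showed no member of 11 past the threshold, also adjusted over the list alone (list adjusted p = 0.75), and were called lower without resistant replicate 2 (0.0311). ESAM lost its call without control replicate 1, resistant replicate 1 or resistant replicate 3 (adjusted p up to 0.177). The endothelial list lost its call without either 2020 library (up to 0.0586), and the fibroblast list without either 2020 library, control replicate 2 or resistant replicate 3 (up to 0.0802). The fibroblast list was also not called in 2021 alone (0.0667), with limma voom (0.079), at a mean of at least 1 CPM (0.468) or with no filter (0.866), where its mean log2 fold change relative to all genes turned from -0.67 to 0.52. The endothelial list was not called in 2021 alone (0.0586) or at a mean of at least 1 CPM (0.0933).

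Cholesterol synthesis genes were lower in the resistant line. Of 24 measured genes 15 fell and none rose (17 and 0 adjusted over the list alone; list adjusted p = 2.9e-09, and adjusted p = 0.52 with an estimated correlation), with a median log2 fold change of -0.47. The median was -0.37 in 2020 and -0.53 in 2021. EBP, the sterol isomerase, fell 2.24-fold from 174 ± 16.7 to 77.7 ± 8.93 CPM (log2 fold change -1.17 ± 0.12 SE, adjusted p = 0.00164) and lies in the chromosome X segment. FDFT1, squalene synthase, fell 1.7-fold from 588 ± 55.7 to 349 ± 62.7 CPM (adjusted p = 0.011), a call that ended without resistant replicate 2 or 3 (up to 0.0754). Of 26 unfolded protein response genes 2 fell (2 adjusted over the list alone), and that list was not called (adjusted p = 0.066), but it was called lower without control replicate 2 (0.0473) and with no filter (0.0365).

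Among histone and DNA replication genes, those that passed had fallen. Of 18 replication-dependent histone genes 9 fell and none rose (14 and 0 adjusted over the list alone; list adjusted p = 2.6e-07, and adjusted p = 0.53 with an estimated correlation). H2BC4 fell 1.81-fold from 606 ± 34.4 to 335 ± 45.4 CPM and H3C2 fell 1.78-fold (adjusted p = 0.00575 and 0.00944). Histone genes are close copies of one another, so reads may be shared among them, and 16 of the 18 lie in the chromosome 6 segment. Of 30 DNA replication genes 3 fell (3 adjusted over the list alone; list adjusted p = 0.00096, and adjusted p = 0.55 with an estimated correlation). POLA1, a DNA polymerase alpha subunit in the chromosome X segment, fell 2.06-fold, and MCM3, a helicase subunit in the chromosome 6 segment, fell 1.88-fold (adjusted p = 0.00119 and 0.0022). Of 30 mitosis genes 1 fell (0 adjusted over the list alone; list adjusted p = 0.0011, and adjusted p = 0.61 with an estimated correlation). CCNA2, that member, fell 1.31-fold (adjusted p = 0.0497, and 0.077 under the replicate block). Leaving out any replicate except control replicate 3 ended the call of CCNA2 (adjusted p up to 0.234).

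No member passed the threshold among 28 nuclear-encoded oxidative phosphorylation genes or 34 ribosomal proteins, although both lists were called lower. The first had a median log2 fold change of -0.15 (adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation), at 0.00 in 2020 and -0.24 in 2021. The second had a median of -0.16 (adjusted p = 0.025; adjusted p = 0.84 with an estimated correlation), at 0.17 in 2020 and -0.33 in 2021. Both counts stayed at 0 adjusted over the list alone. Their most abundant members were ATP5F1A, an ATP synthase subunit, at 590 ± 36.3 and 552 ± 50.8 CPM in control and resistant libraries (adjusted p = 0.654), and RPS4X, at 1370 ± 59.9 and 1190 ± 252 CPM (adjusted p = 0.367). The first lost its call without resistant replicate 3 (adjusted p = 0.116) and the second without control replicate 2 or 3 or resistant replicate 3 (up to 0.685). Of 20 glycolysis genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.55). The lactate exporter SLC16A3 rose 2.37-fold to 16.9 ± 3.78 CPM (adjusted p = 0.00342). LDHB, a lactate dehydrogenase subunit (chromosome 12, 21635342 to 21657842, GRCh38), fell from 298, 451 and 95 counts in the control libraries to 2, 2 and 0 in the resistant libraries. Its ratio was 257, with a 95% counting interval of 100 to 947 (adjusted p = 0.00954), and the call ended without either 2020 library (adjusted p up to 0.109).

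Genes lower in the resistant line were concentrated in 2 long chromosome segments. Windows of 25 neighbouring genes placed from the 2021 libraries alone gave a segment from 292487 to 73198853 on chromosome 6 and one from 2828930 to 68725836 on chromosome X (GRCh38). Of 318 genes at a mean of at least 1 CPM in the chromosome 6 segment, 204 fell and 1 rose, with a median log2 fold change of -0.62. Of 172 such genes in the chromosome X segment, 126 fell and 4 rose, with a median of -0.69. The medians in the 2020 pair, which did not place the segments, were -0.57 and -0.72. The rest of chromosome 6 had a median of -0.07 and the rest of chromosome X of -0.25. The same search gave 10 shorter segments of 25 to 58 genes, 7 lower and 3 higher, on chromosomes 9, 10, 11, 12, 19 and X. In the 2020 pair the 7 lower ones had medians of -0.27 to -0.1 and the 3 higher ones of 0.12 to 0.17. Placing from the 2020 pair alone gave 3 segments, nearly the same ones on chromosomes 6 and X and one of 28 genes on chromosome 19, with medians of -0.40 in 2020 and -0.34 in 2021. The segments on chromosomes 6 and X held 338 of the 764 lower genes (44.2%) and 4.04% of the tested genes. Without them 1111 genes passed, 769 higher and 342 lower.

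**Figure D3:**
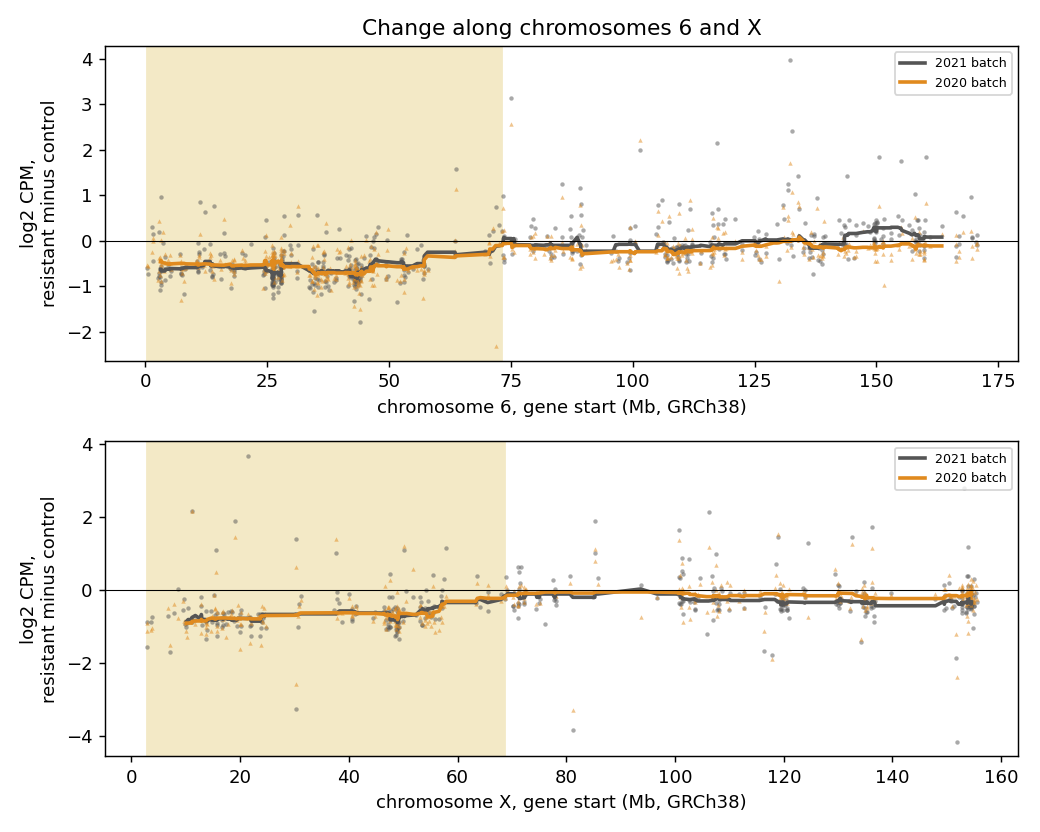
Log2 CPM of resistant minus control (vertical axis) against gene start in Mb for genes at a mean of at least 1 CPM on chromosomes 6 and X, in the 2021 batch (grey circles, 2 against 2) and the 2020 batch (orange triangles, 1 against 1). Lines are medians of 25 neighbouring genes and the shaded spans are the segments placed from the 2021 batch; both lines run below 0 there, with medians of -0.64 and -0.57 on chromosome 6.

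The comparison was repeated within each batch. In the 2021 libraries alone 968 of the same 13950 genes passed, 539 higher and 429 lower, and 946 of them (97.7%, exact binomial 95% interval 96.6 to 98.6) had the same direction in the 2020 pair. Over all tested genes, called or not, 70.1% had the same direction in both batches. The 539 higher genes had a median log2 difference of 1.36 in 2021 and 0.87 in 2020, and the 429 lower genes had medians of -0.83 and -0.70. Across all tested genes, which are not independent replicates, the differences in the 2 batches had a Pearson correlation of 0.70 and a Spearman correlation of 0.57. No gene passed a test of the difference between batches in edgeR, and 2 passed in DESeq2. In edgeR 187 of 13950 genes had an unadjusted p under 0.05, where 698 would be expected with no difference at all. The p-values of that test thus ran high, and its low count is no sign that the batches were alike. With 1 library of each line in 2020, that test has little power.

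**Figure D4:**
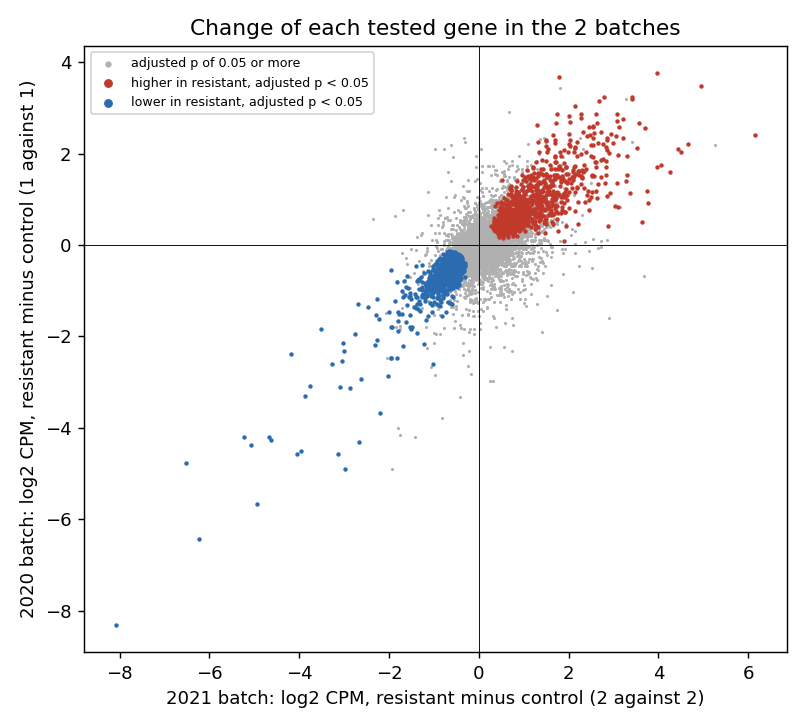
Log2 CPM of resistant minus control (prior count 2) in the 2020 batch (vertical axis, 1 against 1) against the 2021 batch (horizontal axis, 2 against 2), one point per tested gene. Red points were higher and blue points lower in the resistant line at an adjusted p under 0.05, and grey points did not pass; that call uses both batches, and across all points the Pearson correlation is 0.70.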

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

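The crossed block and the fit without the segment genes were chosen after the data were examined. The count of changed genes stayed within 1.5 times of 1633 under both other scalings, both other filters, DESeq2, limma voom, the replicate block (1303 genes) and without the segment genes (1111). It moved to 362 without the batch term and to 1012 in the 2021 batch alone, which has fewer libraries and is filtered here on those 4, leaving 14098 genes, and ranged from 617 to 1985 when each replicate was left out. The count at 2-fold moved to 231 without the batch term, ranged from 333 to 619 over left-out replicates, and was 480 with the replicate block. A crossed block gave 2254 and 692 genes, and the 2254 held all 1633. The 22 called lists became 0 with an estimated correlation and 5 with fry, and 17 to 22 over left-out replicates; the replicate block called the same 22. The share of changed genes that were higher moved from 53.2% to 59.9% under upper quartile scaling, with a shift of the median of all genes of 0.038. Genes differing between batches rose from 0 to 17 without a filter and to 2 with DESeq2. The share of 2021 calls with the same direction in 2020 moved from 97.7% to 92.7% without a filter and to 96.3% with DESeq2. Apart from the constructions named, the cause was not tested. Of 105 called genes that the naming rule takes, all kept their direction under the 15 alternatives fixed beforehand and 25 kept their call under all; the block ended 20 of these calls, no filter 12, upper quartile scaling 7, a mean of at least 1 CPM 5, limma voom 4, the 2021 batch alone 32 and the fit without the batch term 71. The rule also takes 4 genes as the most abundant members of uncalled lists; they were left out after 2 were seen to change sign. Of the 27 uncalled lists, 13 changed direction under some alternative and 9 were called under some, so no direction is given for them in the full set of libraries. CD274, which was not called, changed sign to 0.04 under upper quartile scaling, 0.00 with DESeq2 and 0.34 in 2021 alone, and ranged from -0.14 to 0.34 over left-out replicates. Depth limits CCL2 and CSF2, and 1.5-fold changes were often missed in simulation.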

Other observations

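The tests of copy number, of batches and of a small cell population were chosen after the results they rest on had been seen. So were those of the neighbours of silent genes and of the histone genes. The criterion that leaves both histone explanations open was tightened once their values were known. The counts over other splits and the criterion for GC content were set down before. The segments to which the GC content test was applied, however, came from a search chosen after the data were examined.

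Averaged over both lines, the 2020 libraries held more transcripts of the fixed list of AP-1 and immediate early genes. Of 28 members 25 were lower in 2021, with a median log2 difference of -1.29 (camera adjusted p = 6.5e-06, and adjusted p = 0.56 with an estimated correlation). The list counts given here were not made for each line. Mitochondrially encoded transcripts were lower in 15 of 15 (median -2.90, adjusted p = 7.8e-12, and adjusted p = 0.53 with an estimated correlation) and RNA quality transcripts in 11 of 11 (median -2.55, adjusted p = 0.00044, and adjusted p = 0.69 with an estimated correlation). From 2020 to 2021 the log2 change was -5.11 for NR4A3, an immediate early nuclear receptor, with 32.2 and 50.1 CPM in 2020 and 0.6 to 1.7 CPM in 2021. LIF, a cytokine of the IL6 family, fell from 176.8 and 177 CPM to 6.8 to 29.1 CPM, and KLF6 from 333.3 and 278.9 CPM to 21.2 to 43.4 CPM. The corresponding log2 changes were -3.25 for MAFF, -3.36 for PRDM1, -3.38 for CXCL8 and -4.37 for IL6 (edgeR adjusted p between 1.98e-05 and 0.0254 for these 7). The small structural RNAs RN7SK and RN7SL1 were lower by 4.55 and 3.53 on the same scale. These single genes, and the test of the lists between batches, were chosen after the values were seen.

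A set of 9 genes had at most 3 counts in each resistant library and at least 10 in each control library: GSTP1, LDHB, FLRT2, CRABP1, MCTP2, GRIK3, MT1E, ZNF99 and MYEF2. The reverse held for 4 genes, FLI1, SLC26A9, UPK1A-AS1 and STEAP1, all chosen after their values were seen. Without a stated strand setting, reads of the antisense UPK1A-AS1 cannot be told from those of an overlapping gene. FLRT2 had 35, 292 and 116 counts in the control libraries and none in the resistant libraries, at least 180-fold lower against a floor of 3 counts over the group.

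The lower expression of the segments on chromosomes 6 and X argues against a bias of gene properties and against a batch. The lowest median of 1000 gene sets from other chromosomes, matched on GC content, transcript length and expression, was -0.09 for chromosome 6 and -0.06 for chromosome X. Medians lay at or below -0.57 and -0.68 in both batches. In the 2020 pair, which did not place the segments, 94.3% and 93% of their genes were lower. A candidate explanation is that the resistant line carries fewer copies of these segments, but silencing along them was not tested and no DNA was analysed here.

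For the 9 silent genes, loss of the regions around all of them would lower their neighbours. Pooled over the genes, 66 tested neighbours within 500 kb had a median log2 fold change of -0.05, with 2 below -1. The 24 neighbours of GSTP1 had a median of -0.23, from -1.76 to 0.89. A pooled median cannot decide for the region of a single gene. Loss of single regions, or a loss confined to the genes themselves, therefore remains open. A second candidate explanation is a small population of cells in the control cultures that the resistant line lacks. Between control replicates 2 and 3 the genes' median log2 ratio was 1.61, outside the range of -0.59 to 0.36 that holds 95% of matched sets, which such a population would give. Of the 9 genes, 8 were higher in control replicate 2, and ZNF99 was not, at 0.393 against 0.428 CPM. The ratios of the 9 genes spread from -0.12 to 2.52 (SD 0.83, against a median SD of 0.64 in matched sets). Matched sets hold other genes, so they do not show the spread that one source would give with counting error. Such a population therefore cannot be told apart from separate regulation of each gene.

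The histone decline may follow from position. The 16 histone genes in the chromosome 6 segment had a median of -0.74, just below the range of -0.72 to -0.51 that holds 95% of expression-matched sets from the same segment, by less than the 0.03 spread of the histone median. By batch, all 18 histone genes of the list had medians of -0.505 in 2020 and -0.888 in 2021, against -0.57 and -0.64 for the segment. They thus lay beyond the segment's median in 2021 but not in 2020. Fewer cells replicating DNA remain another candidate explanation. The 28 DNA replication genes outside the segments had a median of -0.21, below the range of -0.12 to 0.06 of matched sets. Matched sets, however, ignore the correlation within the list. The estimated-correlation test gave the whole list an adjusted p of 0.55, but it has little power here and cannot decide. The histone genes elsewhere, H2AC20 and H2BC21 on chromosome 1, changed by -0.41 and -0.16 and did not pass (adjusted p = 0.24 and 0.44).

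With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 split with as many genes: it gave 1633 genes and 560 at 2-fold, and the highest of the others gave 0 for both. Every other split has libraries of both lines in both sets, so the difference between the lines widens its spread. A count of 0 there therefore gives no rate of false calls. For the lists the real split gave 22 and the highest other 18, reached by 2 splits that both keep the 2020 libraries together. Of the 3 other splits that part every same-numbered pair, none called a gene, and they called up to 16 lists.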
